A study of Mus musculus with 7 samples.

How the data were processed

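Total RNA was profiled from 7 samples of CD8 dendritic cells of C57BL/6 mice, which had been isolated by fluorescence-activated cell sorting. RNA was prepared with a column kit and sequencing libraries followed the standard protocols of the instrument maker, per the labels' protocols. The labels place each sample in 1 of 3 populations by its surface level of CD103: CD103 negative (n = 3), CD103 low (n = 2) and CD103 high (n = 2). The CD103 high samples carried the treatment label CpG, a name for DNA motifs that engage Toll-like receptor 9, and are called CpG CD103 high here. The other samples were labelled as untreated. The series' design text calls the samples of each population biological replicates. The tissue, the dose and the time after treatment are not given in the sources used here.

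The labels also give a date for each sample. CpG CD103 high replicates 1 and 2 and CD103 negative replicates 1 and 2 were dated 2012, while CD103 negative replicate 3 and both CD103 low replicates were dated 2013. What was done on these dates is not given in the sources used here. CpG treatment and a high CD103 level occurred in the same samples, so no comparison could part them.

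The deposited files hold raw read counts per gene, 1 file per sample, as whole numbers with no normalization, per the file headers and the values. The tools CASAVA, Subread 1.4.6 and featureCounts and the genome build mm10 are listed, without roles or order, per the submitters' processing notes. The annotation release, the strand setting, the treatment of reads that map to several places and any filter on reads are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense partner could not be told apart. Genes with near-identical copies (Hspa1a and Hspa1b, Tgtp1 and its neighbour, the haemoglobin genes, Lilr4b, Apol7c and members of the H2-Q family) are also uncertain. For these the reason is the unstated treatment of reads that map to several places. A further table of the whole series has 7 columns whose names match no sample label and was not used here.

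Each file listed 27179 genes by Entrez identifier, and 25275 of them (93.0%) matched a symbol in the RefSeq gene table of the same build, from which coordinates were also taken. The unmatched identifiers held 0.533% of all counts and stayed in the tests under their numbers. No row lacked an identifier, and 10722 genes had no count in any library. Total counts ran from 4474211 to 4629181, a ratio of 1.03 between the highest and the lowest. That the totals lie so close is unusual for separate libraries, and the reason is not given in the sources used here. At this depth 3 counts, the upper limit that a count of 0 allows, correspond to between 0.648 and 0.671 CPM, which are counts per 1000000 counts of the library. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

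Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as its factor, which left 10863 genes, and libraries were scaled by trimmed mean of M-values (TMM) factors. A quasi-likelihood model with the group and the date as terms was fitted to all 7 libraries, so that the groups shared 1 estimate of the spread on 3 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F. With the date term, CpG CD103 high was in effect compared with CD103 negative replicates 1 and 2, and CD103 low with CD103 negative replicate 3 alone. The date term itself compared CD103 negative replicate 3 with replicates 1 and 2. The comparison of CpG CD103 high with CD103 low was the difference of those contrasts and thus the test of whether they differ. CPM values are on the TMM-scaled library size, with the SD over libraries of both dates.

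A set of 27 gene lists covered cell identity, other cell types that the sort could hold, antigen presentation, inflammatory signalling, metabolism and RNA quality. Of their 764 entries, 760 were found in the files. Lists with at least 3 measured members, 26 in all, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and adjusted over the 26 lists of each comparison. Camera was repeated with a correlation estimated from the data, and fry was run beside it. The list of sex-linked transcripts had 1 measured member and was not tested.

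The genes named in the text follow a rule. It takes Itgae and Cd8a. It adds the 6 genes of largest rise and the 6 of largest fall among called genes with an average log2 CPM of at least 4, no overlap of CPM between the groups and no predicted name. It also takes up to 3 called members of each list by adjusted p, or the most abundant member where none was called. Other genes were named after their values were seen, and the text says so at each. A few genes that were picked are not reported here. The samples, tests, lists, rule and most alternatives were fixed before the data were examined.

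The alternatives were relative log expression scaling, no filter, a filter of at least 5 CPM in 2 libraries, DESeq2 1.42.0, limma voom, no date term, the replicate number as a block, a test against a change of 1.5-fold, each date alone, and leaving out each replicate in turn. Alternatives added after seeing the data were a correction of each library for transcript GC content and gene length by splines of 5 degrees of freedom, a fit without CD103 negative replicate 3 and the date term, and leaving out replicates for the date difference. GC content was known for 95.3% of tested genes.

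Before use, the scripts were tested on simulated counts drawn from the means and library sizes of these samples, with 200 genes changed. For CpG CD103 high against CD103 negative, 32.8%, 79.1% and 90.9% of genes changed by 1.5-, 2- and 4-fold were recovered. There, 18 of 167 calls (10.8%) fell on unchanged genes, above the nominal rate. For CD103 low against CD103 negative the shares recovered were 19.4%, 56.7% and 90.9%, and 6 of 123 calls (4.88%) fell on unchanged genes. For CpG CD103 high against CD103 low they were 4.48%, 34.3% and 77.3%, and 7 of 85 calls (8.24%) fell on unchanged genes. A simulated list of 30 genes changed by 1.5-fold was recovered in the right direction in each comparison. Its genes were drawn independently and no unchanged list was simulated. The simulation thus does not show how camera behaves where genes of a list are correlated.

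Counts of replicates were compared by chi-square within groups. The statistic per degree of freedom lay between 2.99 for the CD103 low pair and 14.3 for CD103 negative replicates 1 and 3, so no library was a second copy of another of its group. Figures were drawn with matplotlib 3.10.9.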

Results

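The transcriptomes of 7 samples of sorted mouse CD8 dendritic cells were compared across 3 levels of CD103, the integrin αE chain encoded by Itgae. CD8 dendritic cells belong to the type 1 conventional subset (cDC1), which takes up dead cells and presents their antigens to CD8 T cells. The series concerns dendritic cells that are paralysed, that is, poor at starting responses, after a systemic inflammatory syndrome. The CD103 negative group held 3 samples and the CD103 low group 2, all untreated. The CpG CD103 high group held 2 samples labelled as treated with CpG. Each library held between 4474211 and 4629181 counts and between 13477 and 13978 genes with a count. The most abundant transcript in every library was Cd74, the invariant chain of MHC class II, with 2.93% to 4.05% of counts.

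The first principal component of log2 CPM took 47.6% of the variance and set both CpG CD103 high libraries apart from the 5 untreated ones. The second took 23.4% and parted the untreated libraries by date.

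**Figure D1:**
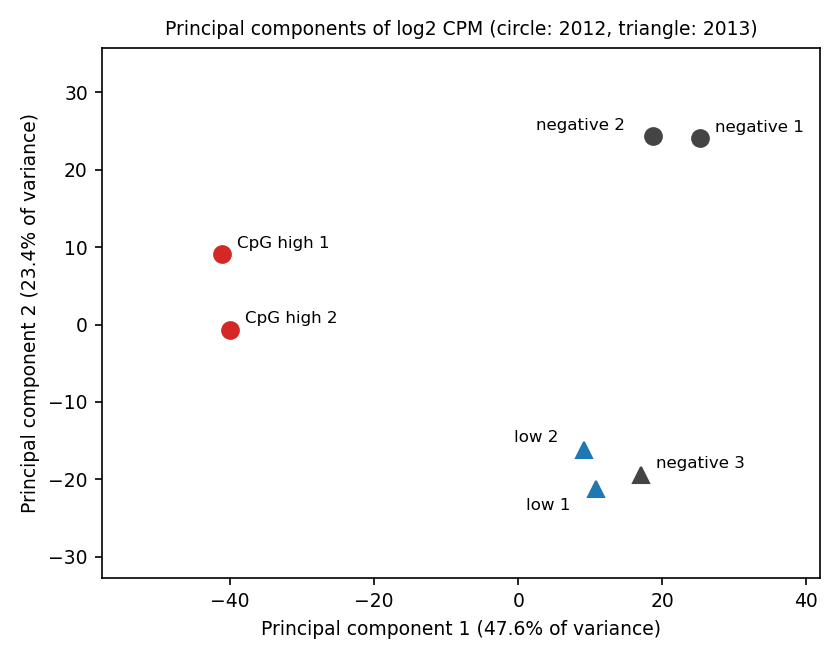
Principal components of log2 CPM over 10863 genes, with 1 point per library, coloured by group (CpG CD103 high red, CD103 low blue, CD103 negative grey) and shaped by date (circle 2012, triangle 2013). The CpG CD103 high libraries lie to the left on the first component (47.6% of variance), and CD103 negative replicates 1 and 2 lie above the untreated libraries of the later date on the second (23.4%).

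Itgae (Entrez 16407, mm10 chromosome 11, 73090505 to 73147449) followed the sort labels. Its level was 59.6 ± 4.61 CPM in CD103 negative cells (SD, n = 3), 360 ± 20.8 in CD103 low cells (n = 2) and 1006 ± 19.6 in CpG CD103 high cells (n = 2). The log2 fold change over CD103 negative was 4.01 (SE 0.09) in CpG CD103 high and 2.73 (SE 0.12) in CD103 low, and the groups differed from each other by 1.28 (SE 0.14). Adjusted p was 1.32e-08, 7.3e-06 and 0.00196. Because cells were sorted on this protein, these values check the labels and are no finding. Cd8a, which encodes the CD8 alpha chain and defines the subset, stood at 1325 ± 63.8, 1383 ± 153 and 1406 ± 31.7 CPM in CpG CD103 high, CD103 negative and CD103 low cells. It passed the threshold in no comparison (CpG CD103 high against CD103 negative, log2 fold change -0.15, SE 0.08, adjusted p 0.17).

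**Figure D2:**
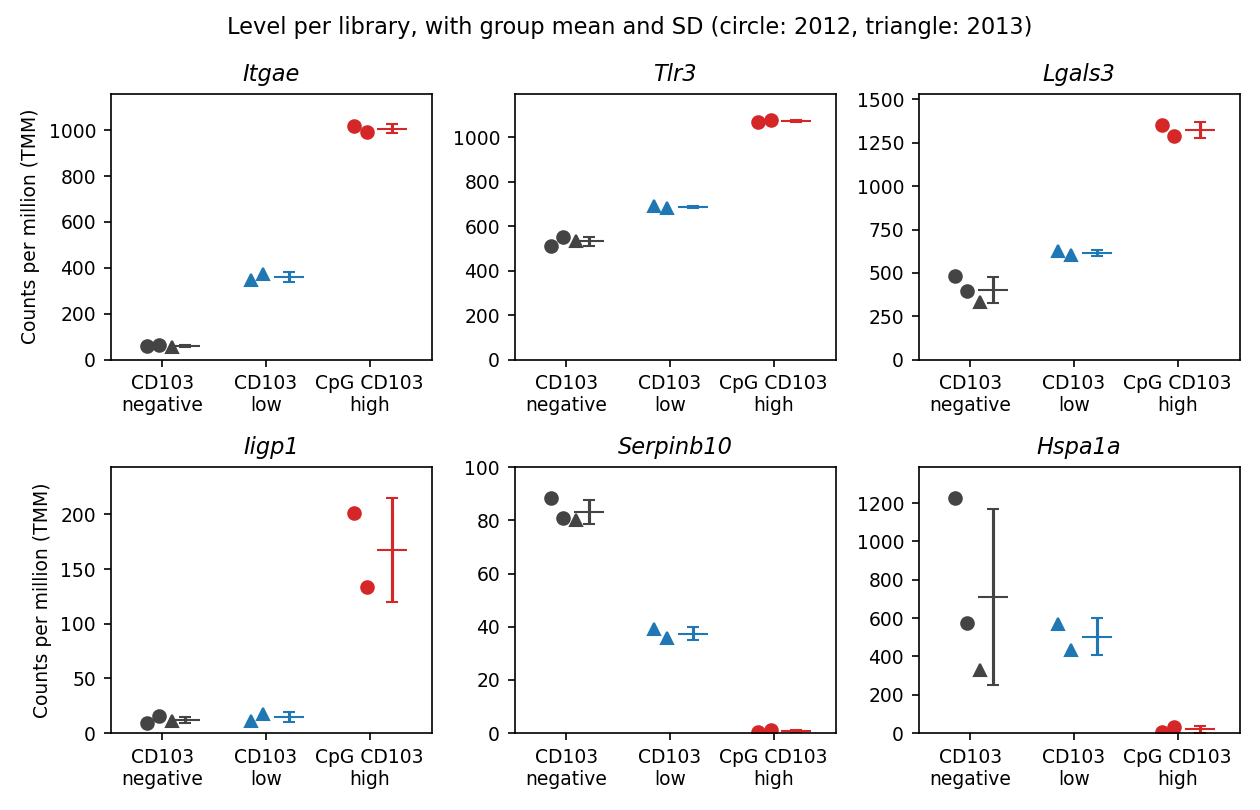
Level of 6 genes in each library in CPM on a linear axis, with 1 point per library (circle 2012, triangle 2013) and the group mean and SD beside the points. Itgae rises from CD103 negative (59.6 CPM) through CD103 low (360) to CpG CD103 high (1006), while Serpinb10 falls from 83.1 through 37.3 to 0.782.

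The comparison of CpG CD103 high with CD103 negative cells asked how dendritic cells after the inflammatory treatment differ from untreated cells without CD103. CpG CD103 high cells held more RNA of Iigp1 and Tgtp1, immunity-related GTPases that interferons induce and that attack the vacuoles of intracellular pathogens. Iigp1 rose from 12.1 ± 2.98 to 167 ± 47.7 CPM (log2 fold change 3.75, SE 0.27) and Tgtp1 rose from 13.1 ± 0.91 to 126 ± 53.5 (3.31, SE 0.28). Dpy19l3, a mannosyltransferase of the endoplasmic reticulum, rose by 3.98 (SE 0.20), from 3.97 ± 0.607 to 67.5 ± 3.79 CPM. The immunoglobulin-like receptor gene Lilr4b and the inflammasome sensor pseudogene Nlrp1c-ps rose by 3.13 (SE 0.32) and 3.08 (SE 0.36). The adjusted p of these genes ran from 2.97e-06 for Dpy19l3 to 0.000376 for Nlrp1c-ps.

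Within the limits on abundance and overlap of the naming rule, the steepest falls were in protease inhibitors of the serpin B cluster on chromosome 1 and in inducible heat-shock proteins. Serpinb10 fell from 83.1 ± 4.49 CPM to 0.782 ± 0.479 (log2 fold change -6.71, SE 0.24, adjusted p 4.69e-07), with 2 and 5 counts in the CpG CD103 high libraries. Its neighbour Serpinb2, which encodes plasminogen activator inhibitor type 2, fell from 47.6 ± 6.62 CPM to 1.00 ± 0.165 (-5.44, SE 0.26), with 4 and 5 counts. Hspa1a and Hspa1b, near-identical genes of the inducible Hsp70 chaperone, fell from 710 ± 462 and 742 ± 483 CPM to 21.4 ± 18.3 and 23.8 ± 16.7 (-5.40, SE 0.51, and -5.29, SE 0.48). The adhesion receptor genes Adgrf5 (3 and 1 counts) and Adgrl3 (6 and 7 counts) fell by 5.06 and 4.46 on the log2 scale (SE 0.58 and 0.33). Folds that rest on so few counts are known only roughly.

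Of 10863 genes, 2860 passed the threshold in this comparison, 1576 higher and 1284 lower, and 782 of them changed at least 2-fold (443 higher, 339 lower). The count fell to 1904 without CpG CD103 high replicate 2, 1696 without CD103 negative replicate 1, 1828 without CD103 negative replicate 2, 1589 without the date term and 1459 with DESeq2. Because the date term leaves CD103 negative replicates 1 and 2 as the control, the spread rests on few libraries of each group, and 518 genes passed a test against a change of 1.5-fold. Of the 2860 genes, 235 were also called in the same direction in CD103 negative replicate 3 over replicates 1 and 2, and 19 in the opposite direction. Both contrasts use replicates 1 and 2 as the control, so some overlap can follow from those libraries.

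Genes of cDC1 identity were mostly higher in CpG CD103 high cells. Of 30 measured members 18 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 1.22e-05, adjusted p = 0.621 with an estimated correlation). Tlr3, a sensor of double-stranded RNA, rose from 532 ± 22 to 1074 ± 6.28 CPM (1.01, SE 0.08), the GTPase gene Septin3 rose by 1.52 (SE 0.13) and the orphan receptor gene Gpr33 by 2.00 (SE 0.18). Xcr1, the chemokine receptor of this subset, was named after its values were seen and rose by 0.71 (SE 0.10, adjusted p 0.0007). The 5 lists that camera called higher in this comparison and the 5 it called lower all lost the call with an estimated correlation, where the lowest adjusted p over the 26 lists was 0.621. Fry called 10 lists here and 0 in either comparison with CD103 low cells. Interferon response (fry adjusted p 0.067), cytokines and chemokines (0.088), cell cycle (0.30) and immediate early and heat-shock genes (0.33) did not pass fry. The B cell, NK cell, glycolysis and integrin lists passed fry but not camera.

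Of 42 measured genes of the type I and II interferon response 20 rose and 0 fell (21 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.000173, adjusted p = 0.724 with an estimated correlation). Beside Iigp1, Zbp1, a sensor of nucleic acids, rose from 24.5 ± 1.30 to 87.0 ± 14.4 CPM (1.82, SE 0.18) and the antiviral GTPase gene Mx1 rose by 1.15 (SE 0.11). The call of Mx1 was lost without the date term (0.66, adjusted p 0.183). In MHC class I presentation 11 of 24 genes rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0113, adjusted p = 0.724 with an estimated correlation). The peptide transporter gene Tap1 rose by 0.83 (SE 0.08), from 640 ± 13.1 to 1142 ± 35.9 CPM. Nlrc5, the transactivator of class I genes, rose by 1.25 (SE 0.11) and H2-Q7, a non-classical class I gene, by 0.77 (SE 0.09). The call of Nlrc5 was lost without the date term (0.86, adjusted p 0.0572).

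Genes listed as associated with tolerance were also higher. Of 23 measured members 12 rose and 0 fell (13 and 3 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.00826, adjusted p = 0.621 with an estimated correlation). Lgals3, the glycan-binding galectin 3, rose from 403 ± 76.3 to 1322 ± 46.2 CPM (1.59, SE 0.10). Entpd1, the surface enzyme CD39 that degrades extracellular ATP, rose by 1.23 (SE 0.10), and Fgl2, a fibrinogen-like secreted protein, by 0.95 (SE 0.09).

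Genes of dendritic cell maturation and migration were lower. Of 28 measured members 16 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 2.52e-05, adjusted p = 0.724 with an estimated correlation). The chemokine gene Ccl5 fell from 123 ± 6.46 to 24.5 ± 1.72 CPM (-2.36, SE 0.11), Apol7c from 872 ± 169 to 129 ± 13.2 (-2.62, SE 0.15) and Fscn1, the actin bundler of mature dendritic cells, from 252 ± 24.6 to 76.6 ± 10.5 (-1.77, SE 0.14). Ccr7, the receptor that guides dendritic cells to lymph nodes, was named after its values were seen and fell by 1.34 on the log2 scale (SE 0.21, adjusted p 0.00141). Among cytokines and chemokines 7 of 21 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.0421, adjusted p = 0.724 with an estimated correlation). Lymphotoxin beta (Ltb) fell by 2.38 and the chemokine gene Ccl6 by 2.16 on the log2 scale (SE 0.28 and 0.23). This list was no longer called when CpG CD103 high replicate 2, CD103 negative replicate 1 or either CD103 low replicate was left out.

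Cell cycle genes were lower in part, with 10 of 44 members falling and 0 rising (10 and 0 adjusted over the list alone) and a median of -0.38 (camera adjusted p = 0.000498, adjusted p = 0.724 with an estimated correlation). The called members led by adjusted p were subunits of the replicative helicase, Mcm6 (-0.92, SE 0.12), Mcm3 (-0.73, SE 0.11) and Mcm4 (-0.85, SE 0.13). The list lost its call without CpG CD103 high replicate 1. Of 39 genes of oxidative phosphorylation 5 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00275, adjusted p = 0.621 with an estimated correlation), and the list lost its call without the date term. Its leading members Atp5o (-0.52), Cox6c (-0.59) and Uqcrc2 (-0.31) lost their calls after correction for GC content and gene length. Of 28 immediate early and heat-shock genes 8 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0204, adjusted p = 0.772 with an estimated correlation). That list lost its call without the date term, without CpG CD103 high replicate 2 and without CD103 negative replicate 1, where its median turned to 0.10.

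**Figure D3:**
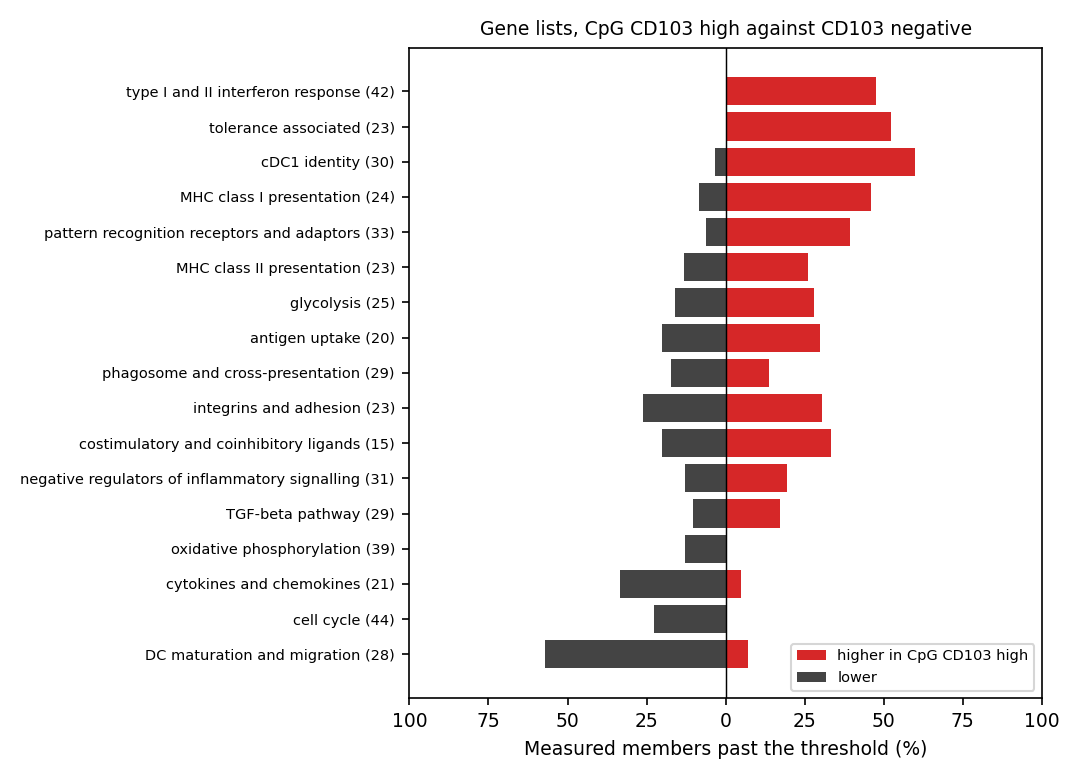
Share of measured members called higher (red, to the right) or lower (grey, to the left) in CpG CD103 high against CD103 negative cells, in percent, for each list of functional genes ordered by median log2 fold change, with the number of measured members in brackets. Interferon response genes are called higher only (20 of 42), and most members of the maturation and migration list are called lower (16 of 28).

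The other functional lists were not called by camera and held genes that moved both ways. Pattern recognition receptors and adaptors had 13 of 33 members higher and 2 lower (adjusted p 0.0636). MHC class II presentation had 6 of 23 higher and 3 lower (0.343), among them the class II transactivator gene Ciita at 0.56 (SE 0.08). Costimulatory and coinhibitory ligands had 5 of 15 higher and 3 lower (0.840). Cd274, which encodes the inhibitory ligand PD-L1, rose from 30.2 ± 5.38 to 66.3 ± 8.83 CPM (1.29, SE 0.15), Tnfrsf14 rose by 0.88 (SE 0.13) and Icosl, the ligand of ICOS, fell by 0.66 (SE 0.09). Negative regulators of inflammatory signalling had 6 of 31 higher and 4 lower (0.909), with Socs1, an inhibitor of interferon receptor signalling, up by 1.88 (SE 0.24) and the repressor gene Bcl6 up by 0.75 (SE 0.10). Glycolysis had 7 of 25 higher and 4 lower (0.495), with the enzyme genes Hk3 and Pfkp up 2.63- and 2.19-fold (log2 SE 0.09 and 0.10). The TGF-beta pathway had 5 of 29 higher and 3 lower (0.836), with its feedback inhibitor gene Pmepa1 up by 1.81 (SE 0.21). Antigen uptake (6 of 20 higher, 4 lower, 0.840), phagosome and cross-presentation (4 of 29 higher, 5 lower, 0.840) and integrins and adhesion (7 of 23 higher, 6 lower, 0.909) were likewise mixed.

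Markers of other cell types moved in this comparison as well. Of 11 measured erythroid and platelet markers 9 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 5.82e-06, adjusted p = 0.621 with an estimated correlation). Haemoglobin transcripts stayed scarce: Hba-a1 stood at 13.5 and 13.2 CPM in the CpG CD103 high libraries, at 1.10 and 0.431 in CD103 negative replicates 1 and 2, and at 0.851 to 5.22 in the later libraries. The neutrophil transcript S100a9 stood at 11.1 and 9.86 CPM in CpG CD103 high and at 2.59 or less in the other libraries. Monocyte and neutrophil markers had 3 of 6 higher and 3 lower (adjusted p 0.815), and macrophage markers 1 of 13 higher and 3 lower (0.815), with Hmox1, haem oxygenase 1, up by 2.32 (SE 0.24) and Vcam1 down (-2.21, SE 0.22). Lower members prevailed among cDC2 markers (4 lower and 1 higher of 14, 0.055), plasmacytoid dendritic cell markers (6 and 2 of 13, 0.209), B cell markers (3 and 0 of 9, 0.386), NK cell markers (2 and 0 of 3, 0.0636) and T cell markers (1 and 0 of 3, 0.288), none of them called as a list. The B cell genes Ms4a1 and Cd22 fell to 8.92 ± 1.01 and 2.90 ± 0.651 CPM from 55.1 ± 12.7 and 25.2 ± 4.06, while Cd79a stood at 1.15 CPM or less in every library.

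The comparison of CD103 low with CD103 negative cells asked what accompanies CD103 without treatment. Apart from Itgae, 5 genes were higher in CD103 low cells. Cst3, the protease inhibitor cystatin C, stood at 13149 ± 319 CPM (n = 2) against 7936 ± 378 (n = 3), a log2 fold change of 0.76 (SE 0.09). Lgals3 rose by 0.89 (SE 0.13), the haemochromatosis gene Hfe by 0.93 (SE 0.14), Fndc5, the precursor of irisin, by 1.02 (SE 0.12) and Pianp by 0.76 (SE 0.11). Among the genes that fell were the chemokine receptor gene Ccr2 (66.7 ± 6.87 to 21.3 ± 4.17 CPM; -1.79, SE 0.17) and Ccl5 (-0.90, SE 0.12). Serpinb10 (-1.10, SE 0.16) and the intermediate filament gene Vim (-0.80, SE 0.09) also fell, and the adjusted p of these 9 genes lay between 0.00562 for Ccr2 and 0.0425.

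A further 4 genes fell: Ly6c2 (-2.12, SE 0.31), Cd7 (-1.52, SE 0.22), Kdr (-2.52, SE 0.38) and L1cam (-2.83, SE 0.40). Ly6c2 falls under the naming rule as a called list member, while Cd7, Kdr and L1cam were named after their values were seen. Levels of all 4 genes in CD103 negative replicate 3, the control of this date, exceeded those in CD103 negative replicates 1 and 2 by 1.87 to 2.94 on the log2 scale. Of plasmacytoid dendritic cell and cDC2 markers with at least 10 counts in all, 13 of 19 and 8 of 19 were at their highest in that library, with Siglech at 19.2 CPM against 0.216 to 4.77 in the others and Cd209a at 21.3 against 0 to 5.29. T cell transcripts stood apart in CD103 low replicate 2, with Trbc2 at 10.6 CPM and Thy1 at 10.3 against 0.908 or less elsewhere.

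In all, 15 of 10863 genes passed the threshold, 6 higher and 9 lower, with 797 at an unadjusted p under 0.05. More genes were higher than lower in some other fits, among them DESeq2 (34 and 6, with 6318 genes given no adjusted p), no date term (8 and 5), and the fits without CD103 negative replicate 1 (8 and 3) or 2 (8 and 4). More stayed lower with relative log expression scaling (6 and 10), the stricter filter (6 and 8) and limma voom (9 and 10). The same held for the 1.5-fold test (1 and 2) and the GC and length correction (15 and 17). The contrast rests on 1 control library, and the calls fell to 4 without CD103 low replicate 1 and to 1 without CD103 low replicate 2, and rose to 31 without CpG CD103 high replicate 1, 24 without CpG CD103 high replicate 2, 290 with the later date alone and 1030 without CD103 negative replicate 3 and the date term. Itgae alone was called in every fit of this comparison that left out a replicate.

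Camera called 12 of 26 lists in CD103 low cells, and none with an estimated correlation, where the lowest adjusted p was 0.348. cDC1 identity was higher as a list, with a median of 0.27 and 27 of 30 members positive (camera adjusted p = 3.22e-07, adjusted p = 0.348 with an estimated correlation), though 0 members passed the threshold over all genes and 6 did adjusted over the list alone. Its most abundant member Ppt1 stood at 0.24 (SE 0.09, adjusted p 0.514). Tolerance associated genes were higher as a list (median 0.32, camera adjusted p = 0.000167, adjusted p = 0.348 with an estimated correlation), with Lgals3 as the member called over all genes. MHC class I (median 0.15), MHC class II (0.16), oxidative phosphorylation (0.07), integrins and adhesion (0.12, with Itgae a member) and erythroid and platelet markers (1.01) were the other lists called higher, with estimated-correlation adjusted p of 0.348 or above. Plasmacytoid dendritic cell markers (median -0.91, camera adjusted p = 6.41e-06, adjusted p = 0.348 with an estimated correlation) and cDC2 markers (-0.79, 0.00246 and 0.510) were lower, as were NK cell markers (-0.90), monocyte and neutrophil markers (-0.55) and maturation and migration genes (-0.16). Without the date term the calls of cDC2, plasmacytoid dendritic cell, monocyte and neutrophil, MHC class I and MHC class II genes were lost, and oxidative phosphorylation (-0.13) and immediate early and heat-shock genes (-0.43) were called lower. With the replicate block the same calls and those of integrins and adhesion and of maturation and migration were lost, cDC2 markers turned to 0.27, oxidative phosphorylation (-0.21), cell cycle (-0.17) and immediate early and heat-shock genes (-0.60) were called lower, and antigen uptake was called higher (0.36). Leaving out CD103 low replicate 1 ended the calls of erythroid and platelet markers, MHC class II and integrins and adhesion, and leaving out CD103 low replicate 2 those of oxidative phosphorylation, integrins and adhesion and monocyte and neutrophil markers. The last were also lost without CD103 negative replicate 1 or 2. Interferon response genes did not move as a list (median 0.01, 0 of 42 called, adjusted p 0.922).

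**Figure D4:**
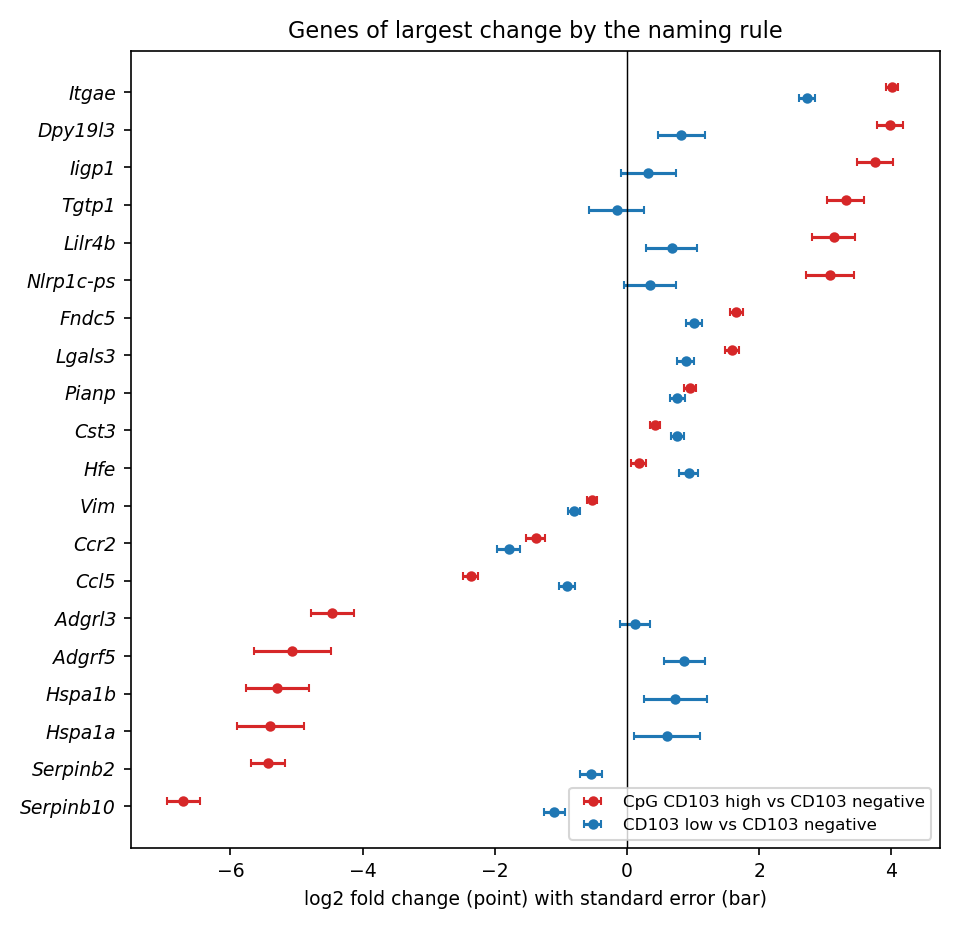
Log2 fold change (point) and standard error (bar) over CD103 negative cells of the genes of largest change reported here by the naming rule in either comparison, for CpG CD103 high (red) and CD103 low (blue). Itgae is higher in both (4.01 and 2.73) and Serpinb10 lower in both (-6.71 and -1.10), while Hspa1a is far lower in CpG CD103 high alone (-5.40).

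The comparison of CpG CD103 high with CD103 low cells tested whether the changes above differed. The GTPase genes Tgtp1 (3.46, SE 0.52) and Iigp1 (3.43, SE 0.52), Dpy19l3 (3.16, SE 0.47), the endocytic adaptor gene Hip1 (2.96, SE 0.29) and the phosphatase gene Ppef2 (2.82, SE 0.23) were higher in CpG CD103 high cells. Hip1 stood at 84.3 ± 2.55 CPM against 14.3 ± 0.36. Hspa1b (-6.02, SE 0.72), Hspa1a (-6.00, SE 0.76), Adgrf5 (-5.93, SE 0.68), Serpinb10 (-5.61, SE 0.34), Gp2 (-5.22, SE 0.49) and Serpinb2 (-4.90, SE 0.34) were lower. Gp2, a receptor for bacterial pili, stood at 2.35 ± 1.75 CPM against 101 ± 31.6. Adjusted p of these genes lay between 4.26e-05 for Serpinb10 and 0.00705 for Iigp1. Within the limits of the naming rule Ly6c2 rose most (4.08, SE 0.42, adjusted p 0.00133), which rested in part on its level of 45.8 CPM in CD103 negative replicate 3. Its call was lost without the date term (1.84, adjusted p 0.16). Ly6c2 stood at 48.4 and 26.9 CPM in CpG CD103 high and at 9.76 and 11.3 CPM in CD103 low.

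Interferon response genes were higher in CpG CD103 high than in CD103 low cells, with 11 of 42 called higher and 0 lower (18 and 1 adjusted over the list alone), a median of 0.62, camera adjusted p = 0.000497 and adjusted p = 0.769 with an estimated correlation. They included Gbp2 (1.48, SE 0.26), Mx1 (1.25, SE 0.17) and Iigp1. cDC1 identity was called higher with 4 members up and 1 down of 30 (median 0.20, camera adjusted p = 0.0432, adjusted p = 0.769 with an estimated correlation), Tlr3 among them (0.65, SE 0.13). Maturation and migration genes were lower, with 9 of 28 down and 1 up (median -0.41, camera adjusted p = 0.0127, adjusted p = 0.769 with an estimated correlation), led by Apol7c (-3.05, SE 0.23), Ccl5 (-1.46, SE 0.17) and Samsn1 (-1.84, SE 0.25). Cytokines and chemokines (4 of 21 down, 0.031), cell cycle (4 of 44 down, 0.000207), oxidative phosphorylation (0 of 39 down, 0.000333) and immediate early and heat-shock genes (5 of 28 down, 0.00218) were called lower, and erythroid and platelet markers higher (0 of 11 called, 0.000333). With an estimated correlation none of these 8 lists passed, the lowest adjusted p being 0.769. Without the date term the calls of cell cycle, oxidative phosphorylation (median -0.0064) and immediate early and heat-shock genes (0.26) were lost, as were the last 2 with the replicate block (-0.01001 and 0.16). Leaving out CpG CD103 high replicate 2 or CD103 negative replicate 1 ended the calls of maturation and migration, cytokines and chemokines, and immediate early and heat-shock genes. Cytokines and chemokines were also lost without CD103 low replicate 2, and cDC1 identity without CpG CD103 high replicate 1, CD103 negative replicate 1 or 2, or CD103 low replicate 1.

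Across all genes 676 passed the threshold, 374 higher and 302 lower. The count was 243 without CD103 negative replicate 1, 111 without CD103 low replicate 1, 165 without CD103 low replicate 2, 382 with DESeq2 and 1667 without CD103 negative replicate 3 and the date term. The groups share no date, so without the date term (870 genes, 386 higher and 484 lower) the date and the group could not be told apart. With it, the ratio of CD103 negative replicate 3 over replicates 1 and 2 enters the contrast. Of the 676 genes, 151 were also called in the same direction in that ratio and 4 in the opposite direction. Part of the calls may thus follow from differences among the control libraries.

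Within the CD103 negative group, replicate 3 is the only library of the later date, so a difference of the dates and a trait of that library cannot be told apart. Against replicates 1 and 2 it held 235 genes that were higher and 141 lower, 376 in all, and 84 passed without CD103 negative replicate 1, 104 without replicate 2, 132 without CD103 low replicate 1, 135 without CD103 low replicate 2, 641 without CpG CD103 high replicate 1 and 603 without CpG CD103 high replicate 2. As lists, cDC2 markers (camera adjusted p 0.00193), plasmacytoid dendritic cell markers (0.00193) and antigen uptake genes (0.00193) were higher in replicate 3. Oxidative phosphorylation (1.83e-07), immediate early and heat-shock genes (4.27e-05) and cell cycle genes (0.000367) were lower. None passed with an estimated correlation, where the lowest adjusted p was 0.472. Xist, the transcript of the inactive X chromosome, stood at 158 and 219 CPM in CD103 negative replicates 1 and 2 and at 365 to 629 in the other libraries, and Ddx3y of the Y chromosome at 0.227 or less in all. Xist was the measured member of the sex-linked list and rose by 1.34 (SE 0.21, adjusted p 0.00143) in CpG CD103 high against CD103 negative cells, a call lost without the date term (0.51, adjusted p 0.52).

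Genes that changed in CpG CD103 high and in CD103 low cells overlapped in part. Against CD103 negative cells, 5 genes were higher and 6 lower in both, where independent lists of these sizes would share 0.87 and 1.06, and 2 were called in opposite directions. The 5 include Itgae, whose rise in both groups was fixed by the sort and is no sign of a shared change. The log2 fold changes of the contrasts had a correlation of 0.20 across genes, which are not independent replicates, a covariance of 0.0555 and the same sign for 52.4% of genes. With the date term the contrasts use different CD103 negative libraries, and 20 simulations of unchanged groups gave a mean correlation of 0.00 (SD 0.02) and a mean covariance of 0.000253. That spread is too narrow to judge the observed value. The CpG ratio and the ratio of CD103 negative replicate 3, over separate control libraries and sharing no treatment, also correlated by 0.23 on average. Without the date term, where the control libraries are shared, the observed correlation was 0.40 and the covariance 0.111, beside 0.38 and 0.027 in simulations with no date difference and -0.26 and -0.0402 in simulations that kept it. The number of genes called in both in the same direction was 18 without CpG CD103 high replicate 1, 3 without CD103 low replicate 1 and 1 without CD103 low replicate 2.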

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

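Leaving out replicates for the date difference, the GC content and length correction, and the fit without CD103 negative replicate 3 and the date term were chosen after seeing the data. In CpG CD103 high against CD103 negative cells, DESeq2 called 1459 genes, no date term 1589 and the test against a 1.5-fold change 518, and leaving out 1 replicate gave 1696 to 2860. In CD103 low against CD103 negative cells, 1 gene passed without a filter, 40 with DESeq2, 3 against a 1.5-fold change, 290 with the later date alone, 32 after GC and length correction and 1030 without CD103 negative replicate 3 and the date term, and leaving out 1 replicate gave 1 to 31. In CpG CD103 high against CD103 low cells these were 263 without a filter, 382 with DESeq2, 104 against a 1.5-fold change and 1667 without CD103 negative replicate 3 and the date term, and leaving out 1 replicate gave 111 to 803. The date term, CD103 negative replicate 3 against replicates 1 and 2, gave 220 genes with DESeq2 and 84 to 641 when 1 replicate was left out. Fewer samples can lower a count by construction where samples were left out; the cause of the rises and of the other changes was not tested. Other scaling, filter and voom fits stayed within 1.5 times of the reported counts.

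Camera with an estimated correlation called 0 lists in each of the 3 comparisons. Leaving out 1 replicate gave 8 to 11, 9 to 13 and 4 to 7 called lists. The correlation of the changes in CpG CD103 high and CD103 low cells was 0.40 without the date term and 0.14 to 0.20 when 1 replicate was left out, and the genes called in both were 1 to 18.

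Replicate numbers were compared as pairs: deviations of same-numbered libraries correlated by 0.21 and 0.05 between CpG CD103 high and CD103 negative, -0.01 and -0.01 between CpG CD103 high and CD103 low, and -0.08 and 0.09 between CD103 negative and CD103 low. Differences of replicates 1 and 2 correlated by 0.17 between CpG CD103 high and CD103 negative over all genes and, a value computed after seeing the data, by 0.79 over 22 immediate early genes, so sets of same-numbered samples at the earlier date are not excluded. With the replicate block in place of the date term, which then also removes the date from the model, 3013, 1175 and 1775 genes were called in the 3 comparisons, and 3385 with the block at the earlier date alone; lists called were 11, 8 and 9, and Itgae stayed at 4.01, 2.53 and 1.48.

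Among named genes and lists, values called in either fit changed direction only where the date term was absent. For lists this is the direction that camera gives against other genes. Of all 2860 genes called in CpG CD103 high against CD103 negative, 7 had the opposite direction after the GC and length correction. In CD103 low against CD103 negative cells the replicate block and the fit without CD103 negative replicate 3 gave Cd7 0.35 and 0.32, Kdr 0.40 and 0.38, Ly6c2 0.12 and 0.0897, and Xist 1.57 and 1.505. Xist in CpG CD103 high against CD103 low was -0.19 without the date term, -0.24 with the block and -0.17 without CD103 negative replicate 3. For such lists the medians without the date term were -0.13 (oxidative phosphorylation) and -0.43 (immediate early and heat shock) in CD103 low against CD103 negative, both called lower, and -0.0064 (oxidative phosphorylation) in CpG CD103 high against CD103 low. With the block the first comparison gave 0.27 for the cDC2 markers list, not called, and the called values 0.36 for antigen uptake, -0.17 for cell cycle, -0.21 for oxidative phosphorylation and -0.60 for immediate early and heat shock. The other gave -1.02 for the cDC2 markers list, called lower, and -0.01001 for oxidative phosphorylation, not called. Without such a change, the median of the immediate early and heat-shock list lost its call and turned to 0.10 in CpG CD103 high against CD103 negative without CD103 negative replicate 1, and to 0.26 and 0.16 in CpG CD103 high against CD103 low without the date term and with the block. Among other values of named genes, 2806 kept direction and side of the threshold, 364 lost the call, 10 gained it and 33 uncalled ones changed sign; of list medians 643 kept both, 72 lost the call, 18 gained it and 63 uncalled ones changed camera direction. Depth limits genes such as Serpinb10, with 2 and 5 counts in CpG CD103 high.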

Other observations

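The tests that follow were chosen after the results they bear on had been seen, except the correlation with separate control libraries, which was set down before its value was computed; the genes and families in this part that the naming rule does not cover were also picked after their values were seen.

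Several genes outside the fixed lists were nearly silent in CpG CD103 high cells. Cd207, the C-type lectin langerin, fell from 62.1 ± 3.38 CPM in CD103 negative cells (SD, n = 3) to 4.12 ± 0.443 (n = 2; log2 fold change -3.93, SE 0.21, adjusted p 4.73e-06), while CD103 low cells held 115 CPM. Tmem176b and its neighbour Tmem176a, membrane channel proteins abundant in immature dendritic cells, fell by 3.98 and 3.05 on the log2 scale (SE 0.26 and 0.17). Mefv, which encodes the inflammasome sensor pyrin, fell from 61.9 ± 16.9 to 3.01 ± 0.81 CPM (-4.12, SE 0.25, adjusted p 8.19e-06).

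Of 74 measured genes of cytoplasmic ribosomal proteins, 42 were called lower and 0 higher in CpG CD103 high against CD103 negative cells, with a median log2 fold change of -0.51 (camera p = 1.89e-08, p = 0.0555 with an estimated correlation). The number called lower was 25 without the date term and 36 after correction for GC content and gene length, where 3 were higher and the median was -0.31. Rplp0 fell from 691 ± 15.6 to 438 ± 25.1 CPM (-0.67, SE 0.10). In CD103 low against CD103 negative cells 0 of the 74 were called (median 0.03), and in CD103 negative replicate 3 over replicates 1 and 2 there were 12 lower and 1 higher (median -0.26). Of 16 measured genes of cholesterol synthesis 7 were lower and 0 higher in CpG CD103 high cells, with a median of -0.40 (camera p = 0.000175, p = 0.0997 with an estimated correlation), and 3 were lower without CD103 negative replicate 1 or with DESeq2, 4 without CpG CD103 high replicate 2 and 4 without CD103 negative replicate 2. Cyp51, a demethylase of that pathway, fell by 0.89 on the log2 scale (SE 0.13).

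The genes lower in CD103 low cells were set apart by their level in CD103 negative replicate 3. Of the 9 genes, 4 were raised there over replicates 1 and 2 by more than 0.5 of their fall, and 1 of them, Ly6c2, was also high in CpG CD103 high (48.4 and 26.9 CPM). In that library 13 of 19 plasmacytoid dendritic cell markers with at least 10 counts in all were at their highest, with Siglech at 19.2 CPM; 4 of the 19 also stand in another list, and 8 had 10 CPM or more on average in CD103 negative replicates 1 and 2. RNA of plasmacytoid dendritic cells in this library is thus a candidate source of those 4 differences, but not the only one. Of cDC2 markers, 8 of 19 were also at their highest there, with Cd209a at 21.3 CPM, and cDC2 as a source was not tested. A sort for CD8 dendritic cells is meant to remove plasmacytoid dendritic cells, and no biological explanation was tested. The other 5 genes, among them Ccr2, Ccl5, Vim and Serpinb10, were set apart by a smaller ratio of that library to replicates 1 and 2, and the source of their falls was not tested.

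Heat-shock transcripts were far lower in CpG CD103 high cells, with a median log2 fold change of -1.30 over 6 members, of which 5 were called lower. A weaker response to handling would lower immediate early genes with them. Against CD103 negative cells the median of 22 such genes was -0.34 (SE 0.19), which lay within neither bound set for it at first. This SE and the next are over genes, which are not independent, and do not measure the spread of libraries. Over all 5 untreated libraries their median log2 ratio was 0.25 (SE 0.16) beside -0.90 for the heat-shock members. It was positive against 4 of these libraries, among which were the 3 of the later date. Against the controls of the same date it was -0.80 for CD103 negative replicate 1 (heat-shock members -1.60) and 0.32 for replicate 2 (-0.89). Those controls disagree in sign and the others differ in date, so whether a weaker immediate early response was the whole cause is undecided. Same-numbered samples of the earlier date shared immediate early levels, with 21 of the 22 genes higher in replicate 1 than 2 in both groups (correlation of the differences 0.79), yet Hspa1a stood at 8.43 against 1225 CPM in replicate 1 and at 34.3 against 574 in replicate 2. A difference in exposure to heat was not tested, and an effect of CpG or of CD103 level, which the design does not part, stays open.

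Long genes tended to be higher in CpG CD103 high cells and in CD103 negative replicate 3, the control of the later date, with Spearman correlations of log2 fold change and gene length across genes of 0.22 and 0.33. Correction for GC content and gene length left 2188 of the 2860 calls (76.5%) in the same direction, which argues against these trends as the whole cause of the calls. The CpG ratio over 1 control library correlated with the ratio of replicate 3 over another by 0.23 on average across genes (0.19 and 0.28 for each arrangement), so an axis between libraries that is not specific to CpG may account for part of the difference. Whether that axis reflects RNA handling or the state of the cells was not tested.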
